A study of Bos taurus with 16 samples.

How the data were processed

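Endometrial RNA of 4 fertile cows was measured at 4 times after parturition, nominally days 10, 30, 50 and 100, with 1 array per cow and time and therefore 16 arrays. Per the labels, tissue pieces came from the uterine horns of the same cows through biopsy forceps, total RNA was extracted, a one-colour spike-in mix was added to it before labelling, and the RNA was labelled with Cy3. The cows are separate animals, so the spread between them includes biological differences, and the 4 arrays of a cow are repeated measurements of that animal. Each cow had its own slide, so this spread also holds any differences between slides and between biopsies.

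The deposited scanner files hold intensity values on a linear scale for 45220 spots per array, of which 1417 are controls. Per the file headers, the processed intensity of each spot was background-subtracted and detrended within the array by Agilent Feature Extraction 11.5.1.1, with surrogate values for low signals and no scaling between arrays. The submitters' processing notes name Agilent Feature Extraction 10.5.1.1, and the source of this difference is not given in the sources used here. The deposited files also give each spot's mean intensity, its local background intensity, and other columns of 0 and 1 that mark spots well above background, saturated or nonuniform, per the file headers. The authors also deposited a value table on a log2 scale. Set against the scanner values it was the log2 processed signal shifted by each array's percentile 75 and centred on each probe's median, with correlations across probes of 0.9998 to 1 and column medians from -0.16 to 0.21, so its scale, centring and direction are known from this comparison. It served as an alternative.

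From the 43803 spots that are not controls, those marked nonuniform on an array were left out there, between 4 and 125 per array. Processed signals were put on the log2 scale, the array's percentile 75 was subtracted, and spots of 1 probe were averaged, which gave 43653 probes. A level in the text is this log2 value relative to the percentile 75 of its array. Probes well above background on at least 4 of the 16 arrays were tested, which kept 33182 probes and left out 10471. No spot was saturated. The share of probes well above background ran from 61.1% to 76.9%, and the number of arrays limits the precision of every value. The median standard error of a log2 difference between 2 times was 0.36.

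Gene names in the scanner files are those of the array design. Of the 43653 probes, 22202 were named through an accession in the reference gene table of assembly ARS-UCD2.0, 1171 through a gene ID and 402 through a synonym, 9849 already had a current symbol, and 10029 kept the name in the file. In all, 33208 probes carried a gene symbol, with 16083 distinct symbols, and 10445 did not. Probe coordinates are those of the deposited files, on bovine build HGSC Btau_3.1 per the file headers. Positions relative to exons were not analysed here.

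Each probe was fitted with limma 3.58.1 in R 4.3.3 with terms for time and cow and moderated statistics, with 9 residual degrees of freedom per probe before moderation. The 6 differences between times and an F test over all times were tested two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 on the adjusted p. The labels number the cows and state that the 4 biopsies came from the same individual, so the pairing is by animal. Deviations from the time means correlated across probes with a median of 0.12 within a cow over 24 pairs and -0.04 between cows over 72 pairs.

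There were 29 gene lists, written before the data were examined together with the tests and the rule for naming genes. The 16 pathway lists were collagens and matrix proteins, matrix proteases and inhibitors, lysosomal proteins, cytokines and chemokines, antimicrobial and acute phase proteins, complement, antigen presentation, interferon response, prostaglandin synthesis and reception, steroid receptors and steroid response, uterine gland secretions, insulin-like growth factors, angiogenesis, cell cycle, immediate early genes and cholesterol synthesis. The 13 cell type lists were neutrophil, macrophage, T and NK cell, B and plasma cell, mast cell, luminal and glandular epithelium, ciliated epithelium, squamous epithelium, stromal fibroblast, smooth muscle, endothelial cell, erythroid cell and trophoblast. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. This used the probe with the highest mean signal of each of 13104 genes, with adjustment over 174 tests of list and difference. The test was repeated with a correlation estimated for each list, and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. Members were counted as risen or fallen after adjustment over all probes and also adjusted over the list alone. The level of a list on an array is the mean over its members of the level minus the member's mean over all arrays.

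The named genes are those with adjusted p under 0.05, the same sign in all 4 cows and a gene symbol that is not a placeholder. They are the 10 largest rises and 10 largest falls for day 30 and day 100 against day 10, and the 5 and 5 largest for the other differences, each with the probe of highest mean signal. Up to 4 members of each list with the largest change among those past the test were added, or up to 2 with the smallest p where none passed. Where a probe was not well above background on any array of 1 group, the change is given as a bound, at least N-fold, from the mean of the brighter group. The dimmer group enters it with, for each array, the higher of the probe's own level and the lowest level among probes well above background.

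The fits were tested on simulated data with 200 changed probes among 32891. For day 30 against day 10 they recovered 8% of probes with a true log2 change of 1, 54% at 2, 80% at 3 and 94% at 4, with 9 false calls. For day 100 against day 10 the shares were 8%, 48%, 78% and 94%, with 11 false calls. Of 28 unchanged lists in the simulation for day 30 against day 10, 0 were called by camera, and the list lowered in the simulation was called. The simulated errors were independent between genes. In the real data the estimated correlation was 0.557 for the macrophage list and 0.674 for collagens and matrix proteins. The simulation therefore cannot tell how often camera falsely calls lists whose genes move together. The real arrays also differed in spread, with limma array weights from 0.219 (day 100, cow 1) to 7.87 (day 50, cow 1). How such differences change the recovered shares and false calls was not tested. These rates may therefore not hold for the real data.

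The alternatives were the fit without the cow term, the cow as a random effect, quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter requiring all 16 arrays, array weights, each cow left out in turn, only the 8 arrays of the 2 times compared, a change of at least 2-fold, and 1 probe per gene. Each slide held the 4 arrays of 1 cow, so a slide term is the cow term. Positions 1 to 4 on every slide held days 10, 30, 50 and 100 in that order, so position and time cannot be told apart by design. Tables and plots used version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.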

Results

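Gene expression was measured in endometrium, the lining of the uterus, of 4 fertile cows during the weeks after parturition. Each cow was biopsied at nominal days 10, 30, 50 and 100, with true sampling days of 9 to 10, 29 to 30, 49 to 51 and 99 to 100. The comparisons ask how expression differed between these times, and a cow was always compared with itself. Each time is represented by 4 arrays, 1 per cow. The median processed signal of an array ran from 51.1 to 154, with the lowest values of 51.1 and 54.8 in cows 3 and 2 at day 100. Replicate arrays correlated across probes with r of 0.90 to 0.98 at day 10, 0.93 to 0.96 at day 30, 0.94 to 0.98 at day 50 and 0.83 to 0.96 at day 100. Probes are not independent replicates.

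The biopsies differed in their cell make-up within each time. The marker lists of epithelium, which lines the lumen and glands, and of smooth muscle, the tissue of the underlying uterine wall, spread most at day 100. In cow 2 at day 100 the epithelial list stood at -3.96 and the smooth muscle list at 2.12, as mean log2 level relative to all arrays. In cow 1 at day 100 the values were 2.78 and -3.54. At day 50 the epithelial list varied least, 0.93 ± 0.26 (SD, n = 4), against 0.05 ± 2.85 (SD, n = 4) at day 100. The neutrophil list stood at 2.99 and 2.80 in cows 1 and 4 at day 10, and at 0.39 and 0.13 in cows 2 and 3. The leading component of the tested probes with a value on every array carried 29.97% of the variance and the next 20.6%.

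**Figure D1:**
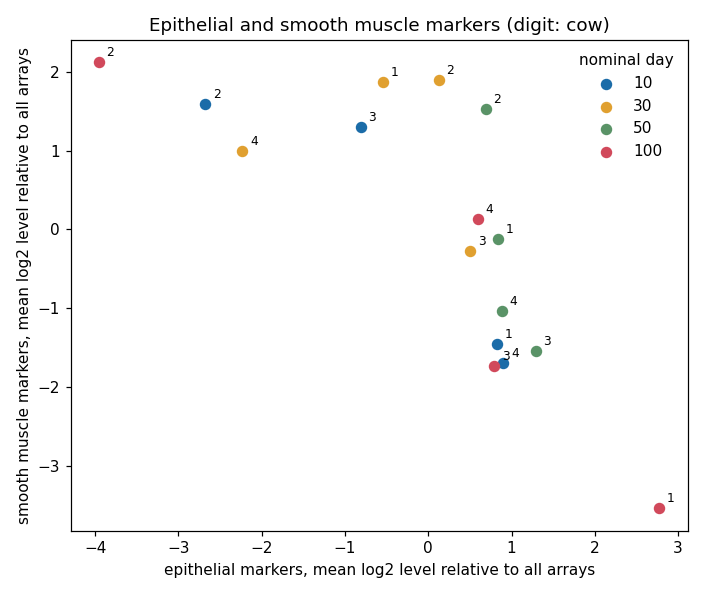
Mean log2 level of the epithelial marker list (horizontal axis) against that of the smooth muscle marker list (vertical axis), both relative to the mean over all arrays, with 1 point per biopsy, coloured by nominal day and numbered by cow. The day 100 biopsies of cow 2 (-3.96 and 2.12) and cow 1 (2.78 and -3.54) lie at opposite ends.

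Between day 10 and day 30 MMP3, MMP1 and MMP13, matrix metalloproteinases that degrade extracellular matrix, had the 3 largest falls among the named genes. MMP3, or stromelysin, was at least 1380.6-fold lower at day 30, where its probe was not well above background in any of the 4 cows, and its measured mean went from 3.69 ± 0.57 to -7.96 ± 0.68 (SD, n = 4, limma adjusted p = 1.21e-06). MMP1, a collagenase that cleaves fibrillar collagen, fell by 8.30 ± 0.63 on the log2 scale (SE, 4 cows, adjusted p = 0.000205). MMP13, another collagenase, fell by 7.74 ± 0.77 (SE, adjusted p = 0.00138), with 1 of 4 arrays well above background at day 30. MMP12, the macrophage elastase, was at least 14.0-fold lower (adjusted p = 0.000472), and the gelatinase MMP9 fell by 4.50 ± 0.49 (SE, adjusted p = 0.00252). Each of these genes fell in 4 of 4 cows. The MMP12, MMP3, MMP1 and MMP13 probes lie on chromosome 15 of build Btau_3.1, at 4717048 to 4717107, 4733287 to 4734269, 4792583 to 4792641 and 4627334 to 4627393.

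The other large falls were in genes of varied function. IL1RN, which encodes the antagonist of the interleukin-1 receptor, fell by 4.40 ± 0.68, and SIGLEC1, a sialic acid receptor of macrophages, fell by 4.06 ± 0.55 (SE, adjusted p = 0.0222 and 0.0131). TRPA1, a cation channel, fell by 5.63 ± 0.56 with 2 of 4 arrays well above background at day 30 (adjusted p = 0.00138). PMEL, known as a structural protein of melanosomes, fell by 4.12 ± 0.76, and the membrane protein TM4SF4 fell by 4.22 ± 0.75, the latter measured on 3 arrays at day 10 and 1 at day 30 (adjusted p = 0.0472 and 0.0413). The named rise was that of the ribosomal protein gene RPL22, by 1.93 ± 0.31 (adjusted p = 0.0281), measured by a probe that the array design names LOC616065. All 11 of these genes moved the same way in 4 of 4 cows.

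Macrophage markers fell as a group. Of 16 measured members 6 fell and 10 did not pass over all probes, and 15 fell when adjusted over the list alone. CSF1R, the receptor that macrophages need for survival, fell by 2.43 ± 0.28 (adjusted p = 0.00376), the myeloid transcription factor SPI1 fell by 2.35 ± 0.35 (0.0189), the immunoglobulin receptor FCGR1A fell by 2.68 ± 0.45 (0.033) and the lysosomal membrane protein CD68 fell by 2.17 ± 0.37 (0.033). The median change was -2.02 and camera gave an adjusted p of 8.19e-18. This call was lost with an estimated correlation, at an adjusted p of 0.506, while fry gave 0.00542. Of the 16 members, 5 are also in another list.

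Lists of matrix and inflammatory genes were also placed lower by camera. Of 26 matrix proteases and inhibitors 5 fell and 21 did not pass, and 11 fell adjusted over the list alone, with a median of -1.04 (camera adjusted p = 1.92e-10, adjusted p = 0.506 with an estimated correlation). Of 38 cytokines and chemokines 3 fell and 35 did not pass, and 15 fell adjusted over the list alone. Beside IL1RN these were the monocyte-attracting chemokines CCL8, which fell by 3.94 ± 0.68 (SE, adjusted p = 0.0359), and CCL3, which fell by 2.28 ± 0.37 with 3 of 4 arrays well above background at day 30 (adjusted p = 0.0297). The cytokine list had a median of -1.56 (camera adjusted p = 1.21e-11, adjusted p = 0.506 with an estimated correlation). Its level went from 2.01 to -0.87 in cow 1 and from 2.73 to -0.48 in cow 4, the cows with the highest neutrophil level at day 10, and from -0.22 to -0.26 in cow 2. Of 26 lysosomal proteins 3 fell, CD68, the protease CTSC, which fell by 1.88 ± 0.33 and LAPTM5 of blood-cell lysosomes, which fell by 1.69 ± 0.25, and 16 fell adjusted over the list alone (median -1.05, camera adjusted p = 3.65e-14, adjusted p = 0.506 with an estimated correlation). CD14, a receptor for bacterial lipopolysaccharide, fell by 3.21 ± 0.45 (adjusted p = 0.0148) and was the 1 member of 27 in the antimicrobial and acute phase list to pass, with 3 falling adjusted over the list alone (median -1.77, camera adjusted p = 3.34e-08, adjusted p = 0.506 with an estimated correlation). The co-stimulatory protein CD86 fell by 2.27 ± 0.38 (adjusted p = 0.0323), as 1 of 19 antigen presentation genes, of which 6 fell adjusted over the list alone (median -1.11, camera adjusted p = 1.22e-06, adjusted p = 0.63 with an estimated correlation). The antigen presentation list was lower at day 30 in cows 1 and 4, or 2 of 4, and went from -0.95 to -0.93 in cow 2 and from 0.16 to 0.36 in cow 3.

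In several lists no member passed over all probes. The neutrophil list had 0 of 8 members passing limma and 5 falling adjusted over the list alone, and the complement list 0 of 22 and 6. Camera placed both lower, with medians of -1.57 and -0.79 and adjusted p of 6.48e-05 and 0.00146 (adjusted p = 0.506 and 0.602 with an estimated correlation). The interferon response list had a median of -0.95 and the immediate early genes one of -0.93, with 0 members passing in either count and camera adjusted p of 7.7e-06 and 1.55e-05 (adjusted p = 0.671 and 0.63 with an estimated correlation). The interferon list was lower in 3 of 4 cows and went from -1.24 to -0.98 in cow 2. Camera placed 4 lists higher at day 30, each with 0 members passing in either count and each higher in 3 of 4 cows. Smooth muscle markers had a median of 1.41 (camera adjusted p = 0.0201, adjusted p = 0.774 with an estimated correlation). The call was lost without cow 1 (adjusted p = 0.34), cow 4 (0.156) or the day 10 array of cow 1 (0.0765). Cell cycle genes had a median of 0.43 and ciliated epithelium markers one of 0.62 (camera adjusted p = 0.00298 and 0.0196, adjusted p = 0.774 with an estimated correlation for both). Both calls were lost without cow 3 (adjusted p = 0.196 and 0.556). Cholesterol synthesis genes had a median of 0.44 (camera adjusted p = 0.000828, adjusted p = 0.753 with an estimated correlation).

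Over all probes limma called 139 changed at day 30, 4 higher and 135 lower, in 2 and 75 named genes, and 4660 had an unadjusted p under 0.05, where 1659 are expected by chance. Leaving out cow 1, 2, 3 or 4 gave 14, 20, 46 and 16 calls, leaving out the day 10 array of cow 1 alone 23, the day 100 array of cow 1 alone 217, and the fit without the cow term 57. Normexp gave 68, array weights 515, the 8 arrays alone 4 and the smooth muscle and epithelium covariate 211, and of the 21 named genes MMP1, MMP3 and MMP12 kept their calls whichever cow was left out.

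**Figure D2:**
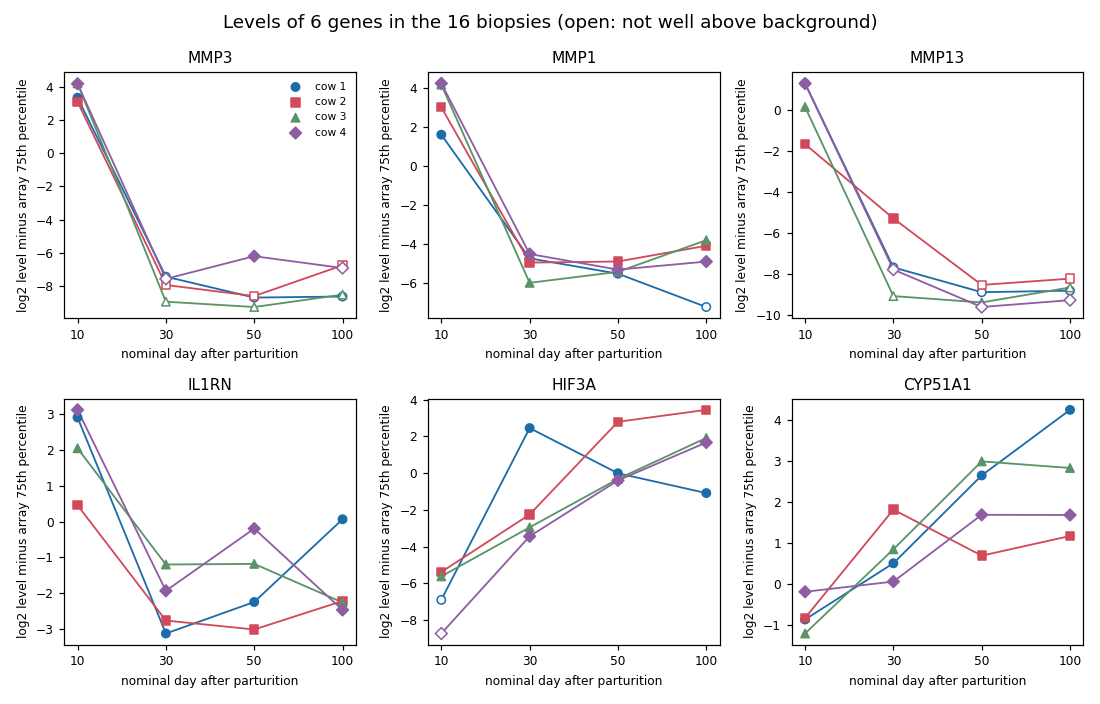
Log2 level minus the array's percentile 75 (vertical axis) of 6 genes at the 4 nominal days (horizontal axis, evenly spaced), with 1 line and symbol per cow and open symbols where the probe was not well above background. MMP3 stood at 3.69 ± 0.57 (SD, n = 4) at day 10 and at -7.96 ± 0.68 at day 30, while HIF3A and CYP51A1 were higher in 4 of 4 cows at day 100 than at day 10.

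Matrix metalloproteinases and an antimicrobial peptide were lower at day 50 than at day 10, and a nodal co-receptor and a hypoxia factor were higher. MMP13 was at least 142-fold lower (adjusted p = 0.000246), MMP12 at least 15.3-fold lower (adjusted p = 0.000126), MMP1 fell by 8.54 ± 0.63 (SE, 4 cows, adjusted p = 0.000126) and MMP3 fell by 11.87 ± 0.53 with 1 of 4 arrays well above background at day 50 (adjusted p = 9.83e-07). TAP, the tracheal antimicrobial peptide, fell by 9.69 ± 1.42 (adjusted p = 0.0144; 1 of 4 arrays above background at day 50), and CCKAR, a receptor for cholecystokinin, fell by 7.98 ± 1.23 (0.0178; 2 of 4). CRIPTO, a co-receptor of nodal signalling that the array design names TDGF1, rose by 10.12 ± 1.86 (adjusted p = 0.0282; 3 of 4 arrays above background at day 10). GJB5, a gap junction protein, was at least 137-fold higher (adjusted p = 0.0427). HIF3A, a hypoxia-inducible transcription factor, rose by 7.17 ± 1.25 (0.0249; 2 of 4 at day 10), the keratin gene KRT24 by 7.02 ± 1.29 (0.0279; 1 of 4 at day 10) and SUSD2, a membrane protein, by 6.75 ± 1.31 (0.0341), all in 4 of 4 cows.

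Macrophage and cytokine lists stood below their day 10 level at day 50. Of 16 macrophage markers 7 fell and 9 did not pass, and 15 fell adjusted over the list alone, with CSF1R changed by -2.02 ± 0.28 (SE, adjusted p = 0.00986) and a list median of -1.71 (camera adjusted p = 4.35e-12, adjusted p = 0.506 with an estimated correlation, fry 0.0115). Of 38 cytokines and chemokines 5 fell, and 10 adjusted over the list alone, among them the neutrophil attractant CXCL8, which fell by 5.54 ± 1.09, and CCL3, which fell by 2.69 ± 0.37 (adjusted p = 0.0357 and 0.01), with CSF2, a growth factor of myeloid cells, at least 12.1-fold lower (adjusted p = 0.0241). That list's median was -1.95 (camera adjusted p = 1.49e-08, adjusted p = 0.602 with an estimated correlation). Of 27 antimicrobial and acute phase genes 3 fell, TAP, the defensin DEFB7, which fell by 5.97 ± 1.12, and CD14, which fell by 3.06 ± 0.45, and 6 adjusted over the list alone (median -1.84, camera adjusted p = 7.7e-06, adjusted p = 0.527 with an estimated correlation). Of 8 neutrophil markers S100A12, a calcium-binding granulocyte protein, fell by 5.14 ± 1.14 (adjusted p = 0.0497), and 5 fell adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.602 with an estimated correlation). Of 26 matrix proteases and inhibitors 7 fell, and 11 fell and 1 rose adjusted over the list alone, with a median of -0.92 (camera adjusted p = 5.37e-07, adjusted p = 0.506 with an estimated correlation). Of 26 lysosomal proteins 4 fell, and 13 adjusted over the list alone (camera adjusted p = 2.43e-11, adjusted p = 0.506 with an estimated correlation).

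Camera placed the mast cell, ciliated epithelium and cholesterol synthesis lists higher at day 50 than at day 10, by calls that were lost with an estimated correlation. Of 7 mast cell markers 2 rose and 5 did not pass, and 5 rose adjusted over the list alone. The mast cell proteases CPA3 and TPSB2 rose by 3.43 ± 0.75 and 2.50 ± 0.55 (SE, adjusted p = 0.0472 and 0.0475), CPA3 with 1 of 4 arrays well above background at day 10. The list median was 1.097 (camera adjusted p = 0.000429, adjusted p = 0.506 with an estimated correlation, fry 0.0437). Of 22 cholesterol synthesis genes 2 rose, the sterol oxidase MSMO1 by 2.15 ± 0.44 and the squalene synthase FDFT1 by 1.74 ± 0.38 (adjusted p = 0.0392 and 0.0482), and 7 rose adjusted over the list alone (median 0.95, camera adjusted p = 2.82e-08, adjusted p = 0.63 with an estimated correlation). Ciliated epithelium markers had 0 of 15 members passing limma and 2 rising adjusted over the list alone, with a median of 1.62, or 1.08 with dim members at their bound (camera adjusted p = 5.18e-05, adjusted p = 0.63 with an estimated correlation). The epithelial list, measured beside these, had a median of 1.05 with 0 of 20 members passing and a higher level in 3 of 4 cows (camera adjusted p = 0.00436, adjusted p = 0.774 with an estimated correlation). The call was lost without cow 2 or cow 3 (adjusted p = 0.0624 and 0.0606).

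Over all probes 544 were called at day 50 against day 10, 194 higher and 350 lower, in 113 and 207 named genes, and 6168 had an unadjusted p under 0.05. Normexp split its 615 calls into 302 higher and 313 lower. Leaving out cow 1, 2, 3 or 4 gave 23, 132, 21 and 149 calls, the day 10 array of cow 1 alone 59, and the day 100 arrays of cow 1 or cow 2 alone 930 and 966. Array weights, highest at 7.87 for the day 50 array of cow 1 and next at 2.75, gave 5246, the 8 arrays alone 884 and the tissue covariate 1284, and of the 37 named genes MMP1, MMP3, MMP12 and MMP13 kept their calls whichever cow was left out.

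At day 100 the matrix protease and macrophage lists were lower than at day 10 and the cholesterol synthesis list was higher, by calls of camera that were lost with an estimated correlation (adjusted p = 0.506, 0.506 and 0.602). MMP3 was at least 1204-fold lower (adjusted p = 1.56e-06), MMP13 at least 131-fold lower (adjusted p = 0.000339), and MMP1 fell by 8.26 ± 0.63 (SE, 4 cows, adjusted p = 0.000216; 3 of 4 arrays above background at day 100). PAMR1, a secreted peptidase-domain protein, fell by 5.74 ± 0.60 (adjusted p = 0.0016) and was well above background on all 16 arrays. HIF3A rose by 8.14 ± 1.25 (adjusted p = 0.0101, 2 of 4 arrays above background at day 10), and DIPK1C, a protein of the secretory pathway with a kinase-like domain, by 6.68 ± 1.02 (adjusted p = 0.00959). TTLL9, a tubulin-modifying enzyme of cilia, rose by 5.11 ± 0.69 (adjusted p = 0.00591), with 1 of 4 arrays well above background at day 10. The probes of PAMR1, HIF3A and DIPK1C lie on chromosomes 15, 18 and 24 of build Btau_3.1, at 65665373 to 65665432, 53385728 to 53385787 and 3968084 to 3968143.

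CCKAR fell by 8.83 ± 1.23, TAP fell by 7.77 ± 1.42, the cobalamin carrier TCN1 fell by 7.75 ± 1.39 and STAR, which moves cholesterol into mitochondria for steroid synthesis, fell by 5.63 ± 1.1998 (SE, adjusted p = 0.00664, 0.0174, 0.0166 and 0.028). CCKAR, TAP and TCN1 were well above background on 1, 2 and 2 of the 4 arrays at day 100. CPB1, a carboxypeptidase, was at least 16.6-fold lower and CLCA3, of a family of chloride channel regulators, at least 17.6-fold lower (adjusted p = 0.00639 and 0.0346). Other rises were those of the metalloprotease MEP1B (8.10 ± 1.87), the ciliary gene CFAP47 (5.23 ± 1.14), SDR16C5, a retinol dehydrogenase (5.35 ± 1.21), MCOLN3, an endosomal cation channel (5.50 ± 1.34), CACNG4, a calcium channel subunit (5.77 ± 1.22), and PRG4, or lubricin (6.46 ± 1.58). At day 10 CFAP47 and PRG4 were well above background on 2 of 4 arrays, and MEP1B, SDR16C5, MCOLN3 and CACNG4 on 3 of 4, so these rises rest in part on dim signals. KCNMB2, a potassium channel subunit, was at least 16.7-fold higher (adjusted p = 0.043). All 20 of these genes moved the same way in 4 of 4 cows.

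**Figure D3:**
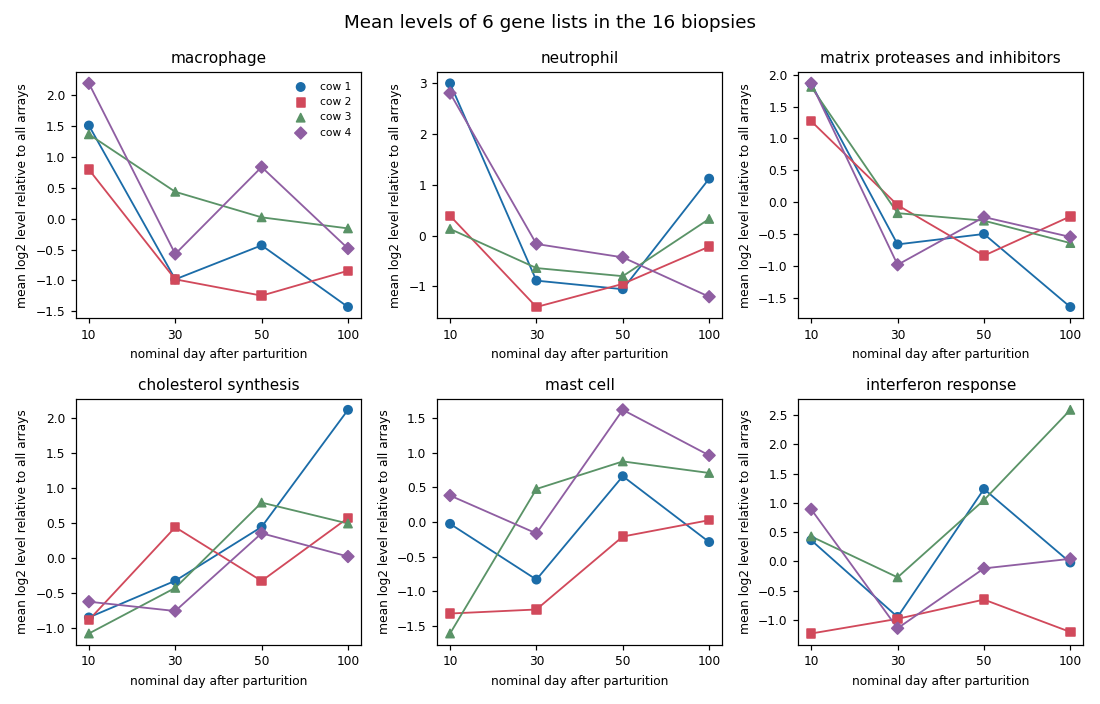
Mean log2 level of the members of 6 gene lists relative to all arrays (vertical axis) at the 4 nominal days (horizontal axis, evenly spaced), with 1 line and symbol per cow. The macrophage list stood at 1.46 ± 0.57 (SD, n = 4) at day 10 and at -0.73 ± 0.54 at day 100, and the cholesterol synthesis list at -0.86 ± 0.19 and 0.80 ± 0.91.

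Of 16 macrophage markers 15 fell at day 100 and 1 did not pass, and 15 fell adjusted over the list alone. The haemoglobin scavenger receptor CD163 fell by 3.21 ± 0.61 (adjusted p = 0.0195; 2 of 4 arrays above background at day 100), FCGR1A fell by 2.92 ± 0.45 (0.0101) and the complement component C1QC fell by 2.53 ± 0.59 (0.0379). The integrin ITGAM was at least 2.46-fold lower (adjusted p = 0.00987), but this dim probe changed by 0.23 (adjusted p = 0.676) with normexp background correction. The list median was -2.25 (camera adjusted p = 3.75e-14, adjusted p = 0.506 with an estimated correlation, fry 0.00542).

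Of 22 cholesterol synthesis genes 9 rose and 13 did not pass, and 14 rose adjusted over the list alone. The sterol demethylase CYP51A1 rose by 3.25 ± 0.63 (adjusted p = 0.0219), the isomerase IDI1 by 3.00 ± 0.54 (0.017) and the squalene epoxidase SQLE by 2.77 ± 0.60 (0.0303). The list median was 1.497 (camera adjusted p = 8.08e-11, adjusted p = 0.602 with an estimated correlation, fry 0.0437). Ciliated epithelium markers had 1 of 15 members rising, CCDC39, needed to assemble cilia, by 3.00 ± 0.59 (adjusted p = 0.0219; 1 of 4 arrays above background at day 10), and 3 adjusted over the list alone. Their median was 1.79, or 1.02 with dim members at their bound (camera adjusted p = 0.00043, adjusted p = 0.671 with an estimated correlation). The level was higher in 3 of 4 cows and went from -1.06 to -1.08 in cow 2.

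Of 28 collagens and matrix proteins 3 fell and 25 did not pass at day 100, and 7 fell adjusted over the list alone. Tenascin C (TNC) fell by 4.88 ± 1.08 and the basement membrane collagens COL15A1 and COL4A2 changed by -2.69 ± 0.56 and -2.63 ± 0.67 (SE, adjusted p = 0.0319, 0.0262 and 0.0492), COL4A2 in 3 of 4 cows. The list median was -0.91 (camera adjusted p = 2.79e-05, adjusted p = 0.671 with an estimated correlation). The call was lost without cow 1 (adjusted p = 0.0855). The list stood at -2.41 in cow 1 at day 100, the biopsy with the lowest smooth muscle level, and at 0.74 in cow 2. Of 15 stromal fibroblast markers, 6 of them shared with another list, HAND2, a progesterone-responsive transcription factor of uterine stroma, fell by 3.05 ± 0.43 (adjusted p = 0.00676; 3 of 4 arrays above background at day 100), and 3 fell adjusted over the list alone (median -0.56, camera adjusted p = 0.0249, adjusted p = 0.757 with an estimated correlation). That call was lost without cow 1 (adjusted p = 0.553), its day 100 array (0.504) or its day 10 array (0.0789), and at day 100 the list stood at -1.70 in cow 1 and between -0.14 and 0.26 in the others.

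Of 26 matrix proteases and inhibitors 10 fell, and 16 fell and 2 rose adjusted over the list alone (median -1.63, camera adjusted p = 3.65e-08, adjusted p = 0.506 with an estimated correlation). Of 22 complement genes 4 fell, the C1q chains C1QA, C1QB and C1QC and the receptor C5AR1, and 7 fell and 1 rose adjusted over the list alone (median -0.72, camera adjusted p = 0.0107, adjusted p = 0.63 with an estimated correlation). The C1q chains are also members of the macrophage list and were counted there. The complement list was lower in 3 of 4 cows. Its call was lost without cow 1 (adjusted p = 0.185), cow 4 (0.0527) or the day 100 array of cow 1 (0.106). Of 26 lysosomal proteins 4 fell, among them the lipase LIPA, which fell by 1.58 ± 0.30 (adjusted p = 0.0206), and 10 fell adjusted over the list alone (camera adjusted p = 5.75e-07, adjusted p = 0.602 with an estimated correlation). Of 27 antimicrobial and acute phase genes TAP and CD14 fell, and 8 adjusted over the list alone (camera adjusted p = 5.2e-05, adjusted p = 0.602 with an estimated correlation). Cytokines and chemokines had 8 of 38 members falling, and 10 adjusted over the list alone (median -1.57, camera adjusted p = 6.43e-07, adjusted p = 0.608 with an estimated correlation). The neutrophil list was not called at day 100, with 0 of 8 members falling and 4 adjusted over the list alone (camera adjusted p = 0.0613). Its level was 0.006 ± 0.97 (SD, n = 4) at day 100 and -0.81 ± 0.27 at day 50. The cell cycle list had a median of -1.34, although RRM1, a ribonucleotide reductase subunit, rose by 1.62 ± 0.38 as the 1 of 41 members to pass, with 0 adjusted over the list alone (adjusted p = 0.0383, list camera adjusted p = 0.00556, adjusted p = 0.798 with an estimated correlation). The list call was lost without cow 2 (adjusted p = 0.066).

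Over all probes 1525 were called at day 100 against day 10, 485 higher and 1040 lower, in 284 and 614 named genes, and 8546 had an unadjusted p under 0.05. Normexp split its calls into 1465 higher and 553 lower with the median of all probes at 0.25, and quantile normalization into 643 higher and 826 lower. Leaving out cow 1, 2, 3 or 4 gave 73, 1583, 83 and 191 calls, the day 10 array of cow 1 alone 256, and the day 100 array of cow 2 alone 3113. Array weights gave 2746, the 8 arrays alone 44 and the tissue covariate 2745, and of the 63 named genes MMP1, MMP3, MMP12, MMP13 and PAMR1 kept their calls whichever cow was left out.

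Between day 30 and day 50 no gene passed the test, and the interferon response and cell cycle lists had the smallest camera p. The interferon response list, genes induced by antiviral signalling, had a median of 1.199 with 30 of 32 members above 0. Its members with the smallest p were GBP4, a guanylate-binding protein, with a log2 difference of 2.77 ± 0.65 (SE, 4 cows, adjusted p = 0.435), and IRF7, a transcription factor, with 1.66 ± 0.43 (adjusted p = 0.435), and 3 members rose adjusted over the list alone. HPGD, the enzyme that inactivates prostaglandins, differed by 4.35 ± 0.69 and PTGFR, the receptor of prostaglandin F, by -4.66 ± 1.19 (adjusted p = 0.435 for both). The interferon list had a camera adjusted p of 8.68e-12 (adjusted p = 0.608 with an estimated correlation), and cell cycle genes a median of -1.06 with 39 of 41 members below 0 (camera adjusted p = 1.52e-06, adjusted p = 0.671 with an estimated correlation). The cell cycle list was lower in 3 of 4 cows and went from -0.69 to 1.66 in cow 4, and its call was lost without cow 3 (adjusted p = 0.0804).

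Cell type lists were also placed apart by camera. The epithelial list had a median of 1.60 (camera adjusted p = 0.000117, adjusted p = 0.671 with an estimated correlation) and the smooth muscle list one of -1.54 (0.000828; adjusted p = 0.671 with an estimated correlation). The mast cell list had a median of 1.06 with all 7 members above 0 and 3 rising adjusted over the list alone (camera adjusted p = 0.000603, adjusted p = 0.506 with an estimated correlation). limma called 0 of 33182 probes, with 3098 at an unadjusted p under 0.05 and a smallest adjusted p of 0.435, and fry called 0 lists. Array weights gave 411 calls and leaving out the day 100 array of cow 2 gave 1.

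Between day 50 and day 100 no gene passed the test, and B cell and immediate early genes stood among the higher lists. JCHAIN, which joins secreted immunoglobulin, differed by 1.38 ± 0.42 (SE, 4 cows) and the B cell cofactor POU2AF1 by 1.44 ± 0.49, both in 4 of 4 cows (adjusted p = 0.912 for both). The B and plasma cell list had a median of 0.23 (camera adjusted p = 0.00822, adjusted p = 0.602 with an estimated correlation). The call was lost without cow 1 (adjusted p = 0.123), cow 4 (0.0509) or the day 100 array of cow 1 (0.16). The immediate early gene list, genes induced within minutes by growth factors or stress, had a median of 0.83 with 20 of 21 members above 0 (camera adjusted p = 1.1e-05, adjusted p = 0.63 with an estimated correlation). Its call was lost without cow 2 (adjusted p = 0.253) or the day 100 array of cow 2 alone (0.493), where the list stood at 1.82, and in cow 3 it stood at -0.10 at day 50 and -0.35 at day 100. limma called 0 probes, with 1039 at an unadjusted p under 0.05, fewer than the 1659 expected by chance, and fry called 0 lists. By camera the macrophage list was lower (median -0.40, adjusted p = 2.22e-05, 0.63 with an estimated correlation), a call lost without cow 4 (0.0958). The cholesterol synthesis list was placed higher, with a higher level in 2 of 4 cows (median 0.53, camera adjusted p = 0.000146, 0.671 with an estimated correlation). That call was lost without cow 1 (0.671) or its day 100 array (0.802). Camera placed the collagen, stromal fibroblast and endothelial cell lists lower (adjusted p = 2.01e-05, 0.00544 and 0.00267; adjusted p = 0.671 with an estimated correlation for all), and the sign of each turned without cow 1 (adjusted p = 0.876, 0.681 and 0.731). The epithelial list was lower (0.00603; adjusted p = 0.774 with an estimated correlation) and turned without cow 2 (0.23), and the cell cycle list (0.000411; 0.757 with an estimated correlation) turned without cow 4 (0.851).

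Between day 30 and day 100 no gene passed the test, and the cell cycle, interferon and cholesterol synthesis lists had the smallest camera p, calls that were lost with an estimated correlation (adjusted p = 0.608, 0.63 and 0.629). The cell cycle list had a median of -1.84 with 38 of 41 members below 0, led by BUB1, a spindle checkpoint kinase, at -2.03 ± 0.54 (SE, 4 cows, adjusted p = 0.259). The cholesterol synthesis list had a median of 1.24, and 10 of its 22 members rose adjusted over the list alone. The interferon list had a median of 1.26 with 31 of 32 members above 0, was higher in 3 of 4 cows and went from -0.98 to -1.21 in cow 2. MX1, an antiviral GTPase, differed by 1.84 ± 0.51 in 3 of 4 cows (adjusted p = 0.267). HBB, the beta chain of haemoglobin, differed by 4.45 ± 1.08 (adjusted p = 0.259), and 4 of 8 erythroid markers rose adjusted over the list alone. The camera adjusted p were 7.4e-12 for cell cycle, 5.85e-09 for cholesterol synthesis and 1.29e-09 for interferon response. Smooth muscle markers had a median of -1.69 with all 13 members below 0 and a lower level in 3 of 4 cows (camera adjusted p = 1.96e-05, adjusted p = 0.649 with an estimated correlation). The call was lost without cow 1 (adjusted p = 0.0743). limma called 0 probes, with 4235 at an unadjusted p under 0.05 and a smallest adjusted p of 0.259, and fry called 0 lists. Normexp gave 16 calls, leaving out the day 100 array of cow 1 gave 1, and leaving out that of cow 2 gave 112, of which 76 were higher and 36 lower. Leaving out all 4 arrays of cow 2 gave 0.

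Over all 4 times the F test called 341 probes, with 6270 at an unadjusted p under 0.05. Leaving out cow 1, 2, 3 or 4 gave 25, 128, 17 and 27, the day 10 array of cow 1 alone 27, and the day 100 array of cow 2 alone 1168. With the cow as a random effect 512 probes passed, with normexp 579, with array weights 2805 and with the tissue covariate 690. Of the 74 list calls made by camera over the 6 differences, 0 held with an estimated correlation, while fry called 6 lists for day 30, 6 for day 50 and 5 for day 100 against day 10. These were macrophage, matrix protease, lysosomal and antimicrobial lists at days 30, 50 and 100, and cytokines at days 30 and 50. The others were neutrophils at day 30, mast cells at day 50 and cholesterol synthesis at day 100. Not called by fry were cholesterol synthesis at day 50 (fry adjusted p = 0.165) and, at day 100, cytokines (0.0688), complement (0.116) and collagens (0.291).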

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

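The values below are those in which 1 of 4 cows lay apart from the others of its time, by a gap, as a share of the range, above Dixon's 95% critical value. The rule was chosen beforehand, and no test in this part was chosen after its result was seen. Of 28 array measures 5 were picked out, of 116 list levels 8 and of 128 levels of named genes 10, and chance alone picks out about 5% of such groups of 4. The array of cow 1 at day 10 had 125 nonuniform spots, with 21 on the next array of that time, that of cow 1 at day 30 had 80 with 10 on the next, and that of cow 4 at day 100 had 53 with 13 on the next. The lowest processed signal was 6.99 in cow 1 at day 10 against 2.03 in the next cow, and 5.01 in cow 1 at day 30 against 2.10.

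Among the lists, antigen presentation stood at 0.36 in cow 3 at day 30, with the nearest other cow at -0.88, and the immediate early genes at -0.13 in cow 4 at day 30 against -0.67. Antimicrobial and acute phase genes stood at 0.75 in cow 1 at day 100 against -0.89, and T and NK cell markers at -1.28 in cow 2 at day 100 against 0.24. At day 10 cow 2 was lowest for matrix proteases and inhibitors, 1.27 against 1.81, and for steroid receptors and response, -0.45 against 0.04. At day 50 the angiogenesis list stood at -0.22 in cow 3 against -0.01, and the insulin-like growth factor list at -0.55 in cow 4 against 0.06.

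Among the named genes, the gelatinase gene MMP9 stood at 2.54 in cow 1 at day 10, with the nearest other cow at 0.37. The metalloprotease gene MEP1B stood at -5.54 in cow 2 at day 100 against 3.87. IL1RN stood at 0.0675 in cow 1 at day 100 against -2.22, and GJB5, not well above background in cows 2 and 3 at day 30, at 0.29 in cow 1 against -6.07. HIF3A stood at 2.80 in cow 2 at day 50 with the next cow at -0.005, STAR at -1.83 in cow 2 at day 50 against -2.83, and TM4SF4 at -6.64 in cow 3 at day 50 against -8.26, well above background in cow 3 alone at that time. KCNMB2 stood at -7.14 in cow 1 at day 10 against -9.03, but it was not well above background on any of the 4 arrays of day 10, and the array of cow 1 had the raised lowest signal given above. It stood at -4.35 in cow 4 at day 50 against -1.66, and CPB1, not well above background in cow 1 at day 30, at -4.20 in cow 3 against -6.02.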

How the results depend on the processing

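The removal of the day 10 array of cow 1 and of the day 100 arrays of cows 1 and 2, and the smooth muscle and epithelium covariate, were chosen only after the data had been seen. Of 121 named gene results 10 kept their direction and call in every setting that tested them, those of MMP1 and MMP3 at all 3 times, MMP12 at day 50, MMP13 at days 50 and 100 and PAMR1 at day 100, and 3 turned direction in some setting. The filter requiring all 16 arrays tested PAMR1 but none of these metalloproteinases. Without the cow block 57 probes passed at day 30, 10 of 21 named genes kept their call at day 30, 29 of 37 at day 50 and 49 of 63 at day 100. With the cow as a random block the F test called 512. A slide block is the cow block, since each slide held 1 cow. Normexp gave 68 at day 30, 16 for day 100 against day 30 and 579 by the F test. Under normexp the change at day 100 was 0.0646 for EDNRB, 0.23 for ITGAM and 0.35 for SLC4A1 (adjusted p = 0.923, 0.676 and 0.457). Dim signal limits these 3 genes, which were well above background on at most 1 array at day 100. Array weights gave 515, 5246 and 2746 at days 30, 50 and 100 against day 10, 411 for day 50 against day 30 and 2805 by the F test, with weights from 0.219 to 7.87, the highest on the day 50 array of cow 1 and the next 2.75. The covariate gave 211, 1284, 2745 and, by the F test, 690. The arrays of the 2 times alone gave 4, 884 and 44, against 139, 544 and 1525 with all arrays. These fits had fewer samples and took the residual spread from the 2 times alone. Fewer samples do not account for the rise at day 50. Most calls at days 30 and 100 depended on having the arrays of the other times in the fit. Counting 1 probe per gene gave 87, 320, 748 and, by the F test, 156, since fewer probes were tested. Quantile normalization, the authors' value table, both other filters and the 2-fold minimum stayed within 1.5 times of every total. The value table holds the same signals up to shifts per array and probe, so its totals could hardly differ. The 2-fold minimum keeps a part of the same calls. Quantile normalization moved the higher calls from 4 to 9 at day 30 and from 194 to 298 at day 50, and the filter requiring all 16 arrays gave 9 at day 30. The cause of the other shifts was not tested.

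Leaving out 1 cow or 1 array gave 14 to 217 calls at day 30, 21 to 966 at day 50 and 73 to 3113 at day 100 against day 10, 0 to 1 for day 50 against day 30, 0 to 112 for day 100 against day 30 and 17 to 1168 by the F test. With an estimated correlation 0 of 74 list calls held. Other settings also ended list calls. Array weights ended 6 of 11 for day 100 against day 50, 5 of 11 for day 100 against day 30 and 4 of 11 for day 50 against day 30. The filter requiring all 16 arrays ended 4 of 12 for day 100 against day 10. For day 100 against day 50, leaving out 1 cow or array gave adjusted p of 1.04e-12 to 0.876 for collagens and matrix proteins, 3.12e-06 to 0.851 for the cell cycle, 2.83e-07 to 0.547 for the epithelium, 3.03e-05 to 0.687 for stromal fibroblasts and 9.79e-06 to 0.874 for endothelial cells. At the upper ends the sign had turned. It also turned without the day 100 array of cow 1 for collagens (0.728), and without cow 1 for stromal fibroblasts (0.681) and endothelial cells (0.731), and without cow 2 for the epithelium (0.23). With the covariate, 3 of 9 list calls for day 50 against day 30 held, 5 were lost and 1 turned. The list that turned was that of T and NK cells (0.697), over a range of 0.00323 to 0.756 in its settings. For day 100 against day 30, 6 of 10 held with the covariate and 4 were lost. The epithelial and smooth muscle lists make up the covariate and were left out of these counts.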

Other observations

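The tests of blood and of macrophage number were chosen only after their results had been seen, and the tissue covariate and the removals of single arrays only after the data had been seen. Growth factor and vessel genes moved in both directions. PGF, placental growth factor, rose by 3.104 ± 0.54 at day 50 and 3.24 ± 0.54 at day 100 against day 10 (SE, limma adjusted p = 0.0249 and 0.0125), and VEGFD, a lymphatic growth factor, by 3.25 ± 0.65 and 3.14 ± 0.65 (0.0363 and 0.0257). ANGPTL4, a lipase inhibitor, fell by 3.05 ± 0.59 at day 100 (adjusted p = 0.0202). Of 28 angiogenesis genes 2 rose and 4 fell at day 100, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.196). IGF2, a fetal growth factor, rose by 1.67 ± 0.40 at day 100 (0.0399) as the 1 of 14 insulin-like growth factor genes to pass in either count (camera adjusted p = 0.62). At day 50, 1 member of that list rose and 3 fell adjusted over the list alone (camera adjusted p = 0.609). The endothelial list had 0 of 17 members passing at day 100 (median -0.42, camera adjusted p = 0.394). The prostaglandin-degrading enzyme HPGD rose by 4.35 ± 0.69 at day 50 and 3.43 ± 0.69 at day 100 (0.0191 and 0.0239), as the 1 of 22 prostaglandin genes to pass, and adjusted over the list alone 1 rose and 3 fell at day 100 (median 0.20, mean -0.35, camera adjusted p = 0.527).

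Hormone response and secretion genes also moved apart. Of 25 steroid receptor and response genes STAR and HAND2 fell at day 100, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.415). At day 50, 3 members of that list rose and 5 fell adjusted over the list alone (camera adjusted p = 0.995). Of 23 uterine gland genes the activin antagonist FST rose by 2.77 ± 0.62 at day 100 and SPP1, or osteopontin, fell by 4.90 ± 0.80 (adjusted p = 0.0323 and 0.0119), and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.653). Camera placed this list lower at day 30 than at day 10 (adjusted p = 0.00632, 0.633 with an estimated correlation). It placed the list higher at days 50 and 100 than at day 30 (adjusted p = 0.00948 and 0.0406, 0.67 and 0.671 with an estimated correlation). Each of these calls was lost without cow 4 (adjusted p = 0.161, 0.078 and 0.129). The call for day 100 against day 30 was also lost without cow 1 (0.499), cow 3 (0.0526) or the day 100 array of cow 1 (0.337). Among 22 T and NK cell markers the protease GZMB rose by 2.26 ± 0.56 at day 100, while NKG7 of cytotoxic granules fell by 2.08 ± 0.39 and the helper T cell marker CD4 fell by 0.81 ± 0.20 (0.0441, 0.019 and 0.0481), and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.381). Camera placed this list lower at day 30 than at day 10 (adjusted p = 0.0137, 0.772 with an estimated correlation), with a lower level in 2 of 4 cows. Of 8 erythroid markers HBB rose by 4.34 ± 1.08 at day 100 and the anion exchanger SLC4A1 fell by 2.00 ± 0.50 (0.0465 and 0.0471), SLC4A1 changing by 0.35 under normexp, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.37). The erythroid level was 1.04 ± 0.56 (SD, n = 4) at day 100, lowest cow 0.62, and -0.32 ± 0.20 at day 10, highest cow -0.05. Whether the day 100 biopsies held more blood was not tested. Of 5 trophoblast markers the transcription factor HAND1 fell by 3.39 ± 0.57 (0.0131), with its other probe of opposite sign, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.765). The squamous epithelium list had 0 of 5 members passing (camera adjusted p = 0.431).

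The fall of the macrophage list from day 10 to day 30, with a median of -2.02, was set against 4 technical explanations. Here the SE of the shares with the covariate and without an array came from leaving out cows in turn. The SE of the erythroid and spiked control values is that over the 4 cows. With the tissue covariate the median was 0.969 ± 0.115 (SE) of its size without it, and without the day 10 array of cow 1 it was 0.901 ± 0.074, so neither accounts for most of the fall. Blood in the day 10 biopsies would have raised erythroid transcripts, and that list was higher at day 10 by 0.267 ± 0.244 on the log2 scale, in 3 of 4 cows, with HBB well above background on 1 of 4 arrays. The spiked controls changed by 0.0761 ± 0.059 of the list's median between slide positions 1 and 2, which speaks against position in the steps after the spike was added, while earlier handling stays open. That fewer macrophages were present at day 30, or that each expressed less, may both hold as hypotheses, and neither was tested.

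MMP1, MMP3 and MMP13 fell further than the macrophage markers between day 10 and day 30. A candidate explanation is that fewer macrophages alone lowered them. The SE in this comparison is that over the 4 cows. The smallest difference from the list's median was -4.70 ± 0.92 (SE), for MMP13 and in 4 of 4 cows, and it was -6.32 ± 1.12 for MMP1 and -8.45 ± 0.60 for MMP3, with signals below the dimmest probe well above background raised to its level, so that the sizes for MMP3 and MMP13 are smaller than their fitted falls give. The 3 genes were picked as the largest falls, so these values exclude nothing. A loss of macrophages and a change in stromal or epithelial expression both stay open.

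No probe was called between days 30, 50 and 100 by limma, with 3098, 1039 and 4235 at an unadjusted p under 0.05 for day 50 against 30, day 100 against 50 and day 100 against 30. Uneven shares of smooth muscle and epithelium could hide differences. With the covariate 0 probes were called between days 30 and 100, and at most 1 with a cow left out as well. The covariate took the median residual SD from 0.511 to 0.462. In the simulation for day 30 against day 10, 8% of changes of log2 size 1 were recovered. A count of 0 therefore cannot exclude hidden differences, and the explanation stays open. Without the day 100 array of cow 2, which had the lowest epithelial level, 112 probes were called, and without all 4 arrays of cow 2 there were 0, with fewer samples in the fit. The part of that array stays open.

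Other splits of the 8 arrays into 4 and 4 were counted for each difference. The real split was the 1 of 35 with as many calls for day 30 (139, highest other 25), likewise 1 of 35 for day 50 (544, highest other 15) and 1 of 35 for day 100 against day 10 (1525, highest other 72). Most of the other splits break the pairing by cow. Of the 8 that keep 1 array of each cow on either side the real one was the 1 as large in each case, with the highest other at 1, 1 and 0, and 8 splits are too few for a share under 0.05. For day 50 against day 30, day 100 against day 50 and day 100 against day 30, 35 of 35 splits gave at least the 0 real calls, which a count of 0 fixes beforehand, so these splits decide nothing. Their highest counts were 74, 2 and 155. For the F test 2 of 100 orders of the times within cows, the real one among them, gave at least the real 341. The highest other gave 1096, several times the real count. Another order of the same arrays can thus give more calls than the real one, and the reason was not identified.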
